A study of Glycine max with 18 samples.

How the data were processed

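Samples and platform. Per the labels, near-isogenic soybean lines that resist bacterial pustule (46, 47, 49) or are susceptible (50, 51, 52) were inoculated with Xanthomonas axonopodis pv. glycines, and leaves were sampled after 3 h, 12 h and 3 days. Each of the 18 arrays carries RNA of inoculated leaves in Cy5 and of non-inoculated leaves of the same line in Cy3. The dyes were not swapped, so a constant dye effect of a probe is part of every comparison of inoculated with non-inoculated leaves. It cancels in differences between genotypes or times and in the comparison of Cy3 levels. The titles give the control no time, while the channel description repeats the time of the array, so whether control leaves were sampled at the same time is not given in the sources used here. Per the labels RNA came from several leaves per sample. The number of plants per sample and the time of day of inoculation and sampling are not given in the sources used here.

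Values used. Per the file headers, spots were scanned and extracted with Agilent Feature Extraction 9.5.3.1 on a custom 4x44K design. The mean signals and median local backgrounds of both channels are intensity values as scanned, per the file headers, and were the input here. The processed signals in the deposited scanner files are intensity values that the software had background-subtracted and dye-normalized, and served as an alternative. The log ratio in the deposited scanner files is a log10 ratio of processed Cy5 over Cy3, and served to find the scale of the deposited value table. The deposited value table of the authors holds log2 ratios of Cy5 over Cy3 that were dye-normalized within arrays, and served as an alternative. On each array it followed the log10 ratio with a slope of 3.18 to 3.32, which is the slope of log2 against log10, with r of 0.988 to 0.999. Its column medians were, for lines 46, 47, 49, 50, 51 and 52, -0.003, -0.004, 0.003, -0.018, -0.029 and 0.01 at 3 h, 0.014, -0.07, -0.08, -0.112, -0.06 and -0.167 at 12 h, and -0.009, -0.013, -0.005, -0.012, 0.001 and -0.002 at 3 days. Empty cells occurred only in columns of 3 of the 5 slides, 33 to 3635 per column, and the filter behind them is not given in the sources used here.

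Slides. Per the file headers the arrays lie on 5 slides. Slide 1 holds resistant lines 46 and 47 at 3 h and susceptible lines 51 and 52 at 3 days. Slide 2 holds resistant line 49 and all susceptible lines at 3 h. Slide 3 holds all resistant lines and susceptible line 50 at 12 h, slide 4 susceptible lines 51 and 52 at 12 h, and slide 5 all resistant lines and susceptible line 50 at 3 days.

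Processing. R 4.3.3 with limma 3.58.1 was used for the statistics, and python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for probe sequences and figures. Backgrounds were subtracted with normexp (offset 50), arrays were normalized with loess, control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged (avereps). Probes well above background in either channel on at least 3 arrays were kept, 39597 of 42564 (93%). A linear model with the 6 groups was fitted in limma with moderated statistics. All 14 comparisons came from fits of this kind, with adjusted p (Benjamini and Hochberg) under 0.05 as the threshold and no limit on fold. The comparison of non-inoculated leaves used Cy3 levels after loess and Aquantile normalization, averaged over the 3 arrays of a line, with 3 against 3 lines. The samples, comparisons, main settings, most alternative settings and 27 gene lists were fixed before the data were examined. Chosen after the files were opened were the motif classes, the fits within single slides and without the dimmest array, and the class tests with motifs of both strands, with line as a block and with slide as a block.

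Named probes. The rule fixed in advance asked for genes with a name, which no probe has. In its place the 2 largest rises and falls of each comparison were taken, with distinct sequences, among probes past the threshold that were well above background on every array in both channels. Their arrays had to share the sign of the mean, or the arrays of both groups had to separate. Motif probes come from the classes described. Identifiers are printed only for the difference of responses at 12 h. SD and n = 3 refer to arrays, 1 per line, and SE to the fit.

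Motif classes. The description of every probe is "Unknown", the reference pairs locus tags and accessions with symbols but none of them with a probe, and so none of the 27 lists matched. Peptide motifs were searched in the 3 forward frames of the 60-base probes in their place. Of 63 motif classes written, 28 had a forward hit, in 95 probes with 86 distinct sequences. The classes were written after the files were opened and before any ratio was computed. The 6 classes with at least 5 distinct sequences (WRKY, NBS, kinase, EF-hand, ubiquitin, histone) were tested as groups with camera, with a preset correlation of 0.01 and each distinct sequence once, in 84 tests adjusted together, of which 10 passed. Only sequences with a value on all arrays entered, 7 of 9 for ubiquitin, 6 of 7 for NBS, 5 of 7 for kinase, 5 of 6 for histone, and all for WRKY and EF-hand. Probes with a forward hit had a median log2 brightness of 10.98 and those with a reverse hit alone 9.75. The same search in the probes read backwards, without complement, gave 1 hit in the classes used. Ubiquitin genes are near-identical, so these probes can bind transcripts of several genes. Some probes of a class share a sequence or are shifted by a few bases, and shifted sequences counted as distinct. This holds for the DDDDSGTLSTSDI pair, the Rubisco pair and some ubiquitin, NBS and WRKY probes. Such copies measure the same target and are not separate evidence.

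Checks. Of 1434 sequences printed on more than one probe, copies differed by a median of 0.07 on the log2 scale, beside a residual SD of 0.46. Within groups the log ratios of arrays had r of 0.39 to 0.46 (resistant 3 h), 0.71 to 0.81 (resistant 12 h), 0.41 to 0.49 (resistant 3 days), 0.52 to 0.65 (susceptible 3 h), 0.75 to 0.83 (susceptible 12 h) and 0.26 to 0.59 (susceptible 3 days). The lowest r of any pair was -0.37, between resistant line 47 at 3 h and resistant line 49 at 3 days. Cy3 levels of the same line at different times had r of 0.961 to 0.993, of other lines of the genotype 0.92 to 0.979, and of the other genotype 0.906 to 0.959. The same lines recur at each time, and residuals of a line at different times had r of 0.03 to 0.61, so the line was added as a block among the alternatives.

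Self-test. With 200 of 39597 simulated probes changed, 46.3%, 70.1% and 98.5% of changes of 1, 2 and 3 log2 units were recovered for resistant leaves at 12 h (151 calls, 8 false). For the difference of responses at 12 h it was 13.4%, 46.3% and 80.3% (95 calls, 2 false), for resistant 12 h against 3 h 20.9%, 46.3% and 87.9% (112 calls, 9 false), and for non-inoculated leaves 1.5%, 31.3% and 83.3% (79 calls, 2 false). With no probe changed 0 calls were made. A shift of 1 log2 unit in the ubiquitin class at 12 h was found in 3 of 3 tests that hold it, with 0 false. The simulated noise was independent between probes and arrays, whereas the ubiquitin class had an estimated correlation of 0.62 in the log ratios. The self-test therefore does not tell how often class tests of the real data call falsely.

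Left out. Tests of gene lists by name and of neighbouring genes were not run, since no probe could be paired with a gene or place. Lists of different times were not compared for overlap as a response, since they may share a control. They were intersected only to look for a constant dye effect.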

Results

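Bacterial pustule of soybean (Glycine max) is caused by Xanthomonas axonopodis pv. glycines. Transcript levels in leaves sprayed with strain 8ra of this bacterium were set against those in non-inoculated leaves on 18 two-channel oligonucleotide arrays. Near-isogenic lines that differ in resistance were used, with resistant lines 46, 47 and 49 and susceptible lines 50, 51 and 52. Inoculated leaves were taken 3 h, 12 h and 3 days after spraying, which gave 6 groups of 3 arrays with 1 array per line and time. On each array the Cy5 channel held inoculated leaves of a line and the Cy3 channel held non-inoculated leaves of the same line, so a positive log2 ratio means a higher signal in inoculated than in non-inoculated leaves. Such a ratio also holds any dye effect of the probe and any change in the non-inoculated leaves. The line was the replicate within each group. The fit of ratios pooled the spread over all 6 groups and had no block for line. Arrays of a line at different times thus counted as independent, and p-values measure a spread shared by all times and both genotypes. The median Cy3 signal per array ran from 427 to 1149 and the median Cy5 signal from 311 to 1206, over a median local background of 37 to 42. Between 68.6% and 92.6% of spots were well above background in Cy3, and between 68.2% and 89.5% in Cy5. The dimmest array was that of susceptible line 51 at 12 h. The number of arrays limits the precision of every value.

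The files used here give each probe an identifier and its 60-base sequence, with the description "Unknown", and pair no probe with a gene. Groups of transcripts are therefore described by peptide motifs that a probe's forward reading frames encode, such as WRKYGQK of WRKY transcription factors. A motif tells the protein family and not the gene. In all, 95 probes carried a motif of 28 classes, and some of them repeat the same stretch. The named motif probes were well above background in both channels on all 18 arrays unless stated otherwise.

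**Figure D1:**
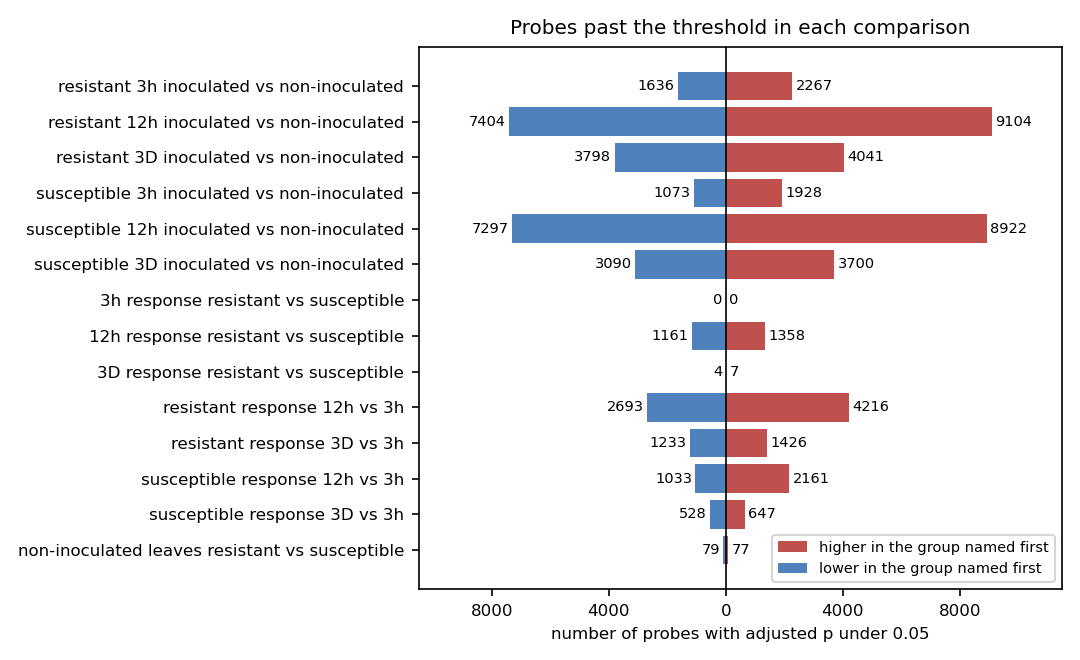
Bars give the number of probes with adjusted p under 0.05 (horizontal axis) in each of the 14 comparisons (vertical axis), to the right for probes higher and to the left for probes lower in the group named first. The longest bars are those of inoculated against non-inoculated leaves at 12 h, with 9104 probes higher and 7404 lower in resistant lines.

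The early response was addressed by the 3 h arrays. In resistant lines both probes with the light-harvesting chlorophyll protein motif NGRLAMFS rose, to log2 ratios of 1.62 ± 1.49 (SD, n = 3) and 1.82 ± 1.40, while the same probes stood at 0.96 ± 0.76 and 1.37 ± 1.30 in susceptible lines without passing the test. Of 10 probes that encode ubiquitin, the small protein that tags others for breakdown, 3 rose in resistant lines and 1 in susceptible lines, none fell, and the medians were 0.60 and 0.45. Adjusted over the list alone the numbers were 6 and 4. In susceptible lines a probe for the Rubisco small subunit, part of the carbon-fixing enzyme, rose by 2.57 ± 1.79, although its Cy5 spot was saturated on 6 of the 18 arrays. A pair of EF-hand probes with the calcium-binding motif DDDDSGTLSTSDI, shifted by a base from each other, lay at -1.65 ± 0.40 and -1.67 ± 0.39 in susceptible lines (limma, adjusted p = 0.00251 and 0.00223). In these lines a cytochrome P450 probe with the motif PFGSGRRVCPG stood at -1.20 ± 0.29. A WRKY probe of the WRKYGKK type fell in resistant lines, to -1 ± 0.89, and none of the other 7 WRKY probes passed. None of the 7 NBS probes, which encode the nucleotide-binding motifs of resistance proteins, passed in either genotype.

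Over all 39597 probes tested, 2267 rose and 1636 fell in resistant leaves at 3 h, and 1928 rose and 1073 fell in susceptible leaves. With median centring the share of rises went from 58.1% to 48.4% in resistant leaves, so that more probes fell, and from 64.2% to 80.1% in susceptible leaves. The ubiquitin class was shifted upward in resistant lines (camera, adjusted p = 0.00569, 7 of its 9 distinct sequences, those with a value on every array) and in susceptible lines (adjusted p = 0.0329). Neither shift held when the correlation between members was estimated, with adjusted p = 0.898 with an estimated correlation in both. With the spread taken from the compared arrays alone, 0 probes passed in either genotype, against 10784 and 8334 at an unadjusted p under 0.05 in the joint limma fit. Without line 46, 47 or 49 the resistant count of 3903 became 996, 395 and 1890, and without line 51 or 52 the susceptible count of 3001 became 50 and 420. It rose to 7949 without background subtraction, 7070 with the scanner's processed signals, 7168 with the deposited values and 7673 with array weights, against 3710, 3144, 3250 and 4907 in resistant lines. Which genotype had more calls at 3 h therefore depended on the processing. Without line 47 none of the light-harvesting, ubiquitin and WRKYGKK calls in resistant lines held, and without line 51 none of the Rubisco, EF-hand, P450 and ubiquitin calls in susceptible lines.

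At 12 h the NGRLAMFS pair had the largest ratios of all motif probes. These probes reached 5.96 ± 0.19 and 6.01 ± 0.26 in resistant lines, or 62.2-fold and 64.4-fold, and 5.75 ± 0.26 and 5.87 ± 0.19 in susceptible lines. The probe with NGRLAMFA stood at 4.71 ± 0.69 and 5.25 ± 0.54. The fourth light-harvesting probe, NGRLAMLA, did not pass in resistant lines (1.28 ± 1.12) and stood at 2.53 ± 0.69 in susceptible lines, with Cy5 saturated on 4 of the 18 arrays. In susceptible lines both Rubisco small subunit probes, shifted by a base from each other, also rose, to 2.61 ± 0.67 and 2.66 ± 2.41. Their Cy5 spots were saturated on 6 and 4 of the 18 arrays, so these sizes are not exact. Neither passed in resistant lines. A probe with the motif RSHAQKFF, found in MYB transcription factors of the LHY and REVEILLE kind that take part in the plant circadian clock, rose by 5.76 ± 0.06 in resistant and 4.97 ± 0.28 in susceptible lines. That probe was well above background in Cy5 on 16 of the 18 arrays, short of the rule for named probes. Naming that probe was therefore a choice made after its values were seen. Its ratios at 3 h were 0.02 ± 0.48 and -0.23 ± 0.16.

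All 10 ubiquitin probes rose in resistant leaves at 12 h, by 0.80 to 1.61, and 2 of 10 in susceptible leaves, where the median was 0.22. An HSP70 probe with the chaperone motif DLGGGTFDVS rose by 1.44 ± 0.23 in resistant lines and 1.69 ± 0.58 in susceptible lines. Among WRKY probes 3 rose and 0 fell in resistant lines, with 0.73 ± 0.31 for one with WRKYGQK, and 1 rose and 3 fell in susceptible lines, with -1.01 ± 0.04 for the WRKYGKK probe. Of the 7 NBS probes 2 rose and 2 fell in resistant lines, and 4 fell in susceptible lines, 2 of them with GMGGLGKTT to -0.98 ± 0.34 and -0.96 ± 0.29. Both protein phosphatase 2C probes rose in resistant lines, by 1.02 ± 0.58 and 1.38 ± 0.40, and a kinase probe with HRDLKPDNLL fell in both genotypes, to -1.38 ± 0.30 and -1.06 ± 0.01. The DDDDSGTLSTSDI pair was again low, at -0.95 ± 0.23 and -0.96 ± 0.19 in resistant lines and -1.47 ± 0.13 and -1.53 ± 0.16 in susceptible lines. With the spread of the 12 h arrays alone none of the 3 WRKY rises and neither of the GMGGLGKTT falls in resistant lines held, and the WRKYGKK fall in susceptible lines was lost when any line was left out.

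In all, 9104 probes rose and 7404 fell in resistant leaves at 12 h, which is 41.7% of those tested, and 8922 rose and 7297 fell in susceptible leaves. With median centring in place of loess the share of rises among called probes was 46.6% in place of 55.1% in resistant and 44.1% in place of 55% in susceptible leaves. The scanner's processed signals gave 49.3% and 47.3% and the deposited values 47.7% and 46.5%, so the direction of the balance was not settled. The ubiquitin class was shifted upward in resistant lines (camera, adjusted p = 0.00236; adjusted p = 0.898 with an estimated correlation) and was not called in susceptible lines (adjusted p = 0.465). From the 3 h to the 12 h arrays 7890 probes changed level in the Cy5 channel of inoculated leaves and 309 in the Cy3 channel of non-inoculated leaves.

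**Figure D2:**
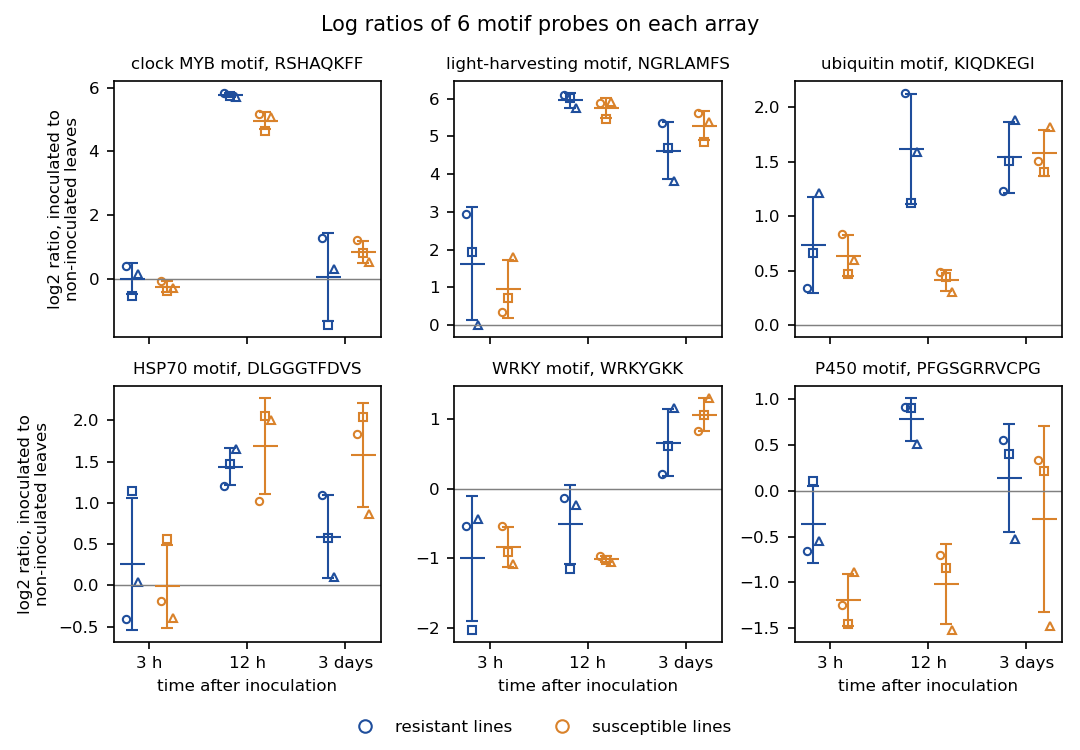
Log2 ratios of inoculated to non-inoculated leaves (vertical axis) for 6 motif probes at 3 h, 12 h and 3 days (horizontal axis), with an open symbol per array and line, resistant lines in blue and susceptible lines in orange, and bars for the mean ± SD of 3 arrays. The clock motif probe stands near 0 at 3 h and at 5.76 and 4.97 at 12 h, and the P450 probe at 0.78 in resistant against -1.02 in susceptible lines at 12 h.

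At 3 days after inoculation all 10 ubiquitin probes had risen in both genotypes, by 0.68 to 1.58 in resistant and by 1.09 to 2.21 in susceptible lines, and all 10 also passed when adjusted over the list alone. The ratios of the NGRLAMFS probes remained high, at 4.62 ± 0.76 and 4.51 ± 1.03 in resistant and 5.29 ± 0.39 and 5.10 ± 0.25 in susceptible lines. Over the 6 lines their Cy3 level changed by -1.96 and -2.45 from 3 h to 3 days, and their Cy5 level by 1.7 and 0.76. The clock motif probe was at 0.06 ± 1.39 and 0.86 ± 0.35 and did not pass. Of 8 EF-hand probes 3 rose in resistant lines, among them DIDKDGKISLPEF at 1.57 ± 0.66 and DTDKDGRISYEEF at 1.35 ± 0.65. In susceptible lines 1 EF-hand probe rose and the DDDDSGTLSTSDI pair fell, to -1.43 ± 0.46 and -1.44 ± 0.44. The WRKYGKK probe, low at 3 h, rose in susceptible lines to 1.06 ± 0.24, and a different WRKY probe rose in resistant lines to 1.57 ± 0.27. An NBS probe with GLPLALK rose in resistant lines, by 1.30 ± 0.28. Both HSP70 probes rose in susceptible lines, by 1.63 ± 0.66 and 1.58 ± 0.63, as did 1 of 3 probes for beta-1,3-glucanase, an enzyme that degrades fungal and plant cell wall glucans, by 1.64 ± 1.68. The glucanase and WRKYGKK calls in susceptible lines were lost when any line was left out.

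The counts at 3 days were 4041 probes up and 3798 down in resistant leaves, and 3700 up and 3090 down in susceptible leaves. The ubiquitin shift had adjusted p = 1.37e-06 in resistant and 8.75e-08 in susceptible lines (camera), and adjusted p = 0.866 with an estimated correlation in both. With the spread of the compared arrays alone 234 and 74 probes passed, with 0 of the 10 ubiquitin probes in either genotype and both NGRLAMFS probes in both. Without line 46 or 49 the resistant count of 7839 was 4156 and 3472, and without line 50, 51 or 52 the susceptible count of 6790 was 3013, 3068 and 3783. Array weights raised the susceptible count to 11612. The share of rises in susceptible leaves was 48% with processed signals or deposited values in place of 54.5%.

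The resistant and susceptible responses overlapped at each time. At 3 h 906 probes rose in both genotypes, where independent lists of these sizes would share 110, and 475 fell in both, against 44. At 12 h the numbers were 5378 against 2051 for rises and 4226 against 1364 for falls, and 289 probes changed in opposite directions. At 3 days they were 1918 against 377 and 1652 against 297, with 27 in opposite directions. Across probes, which are not independent replicates, the mean log2 ratios of both genotypes had a Pearson r of 0.70, 0.72 and 0.61 at the 3 times. The genotypes had their own control leaves, but a dye effect of a probe is common to all arrays and adds to such overlap. Control leaves not matched in time of day to the inoculated leaves would also act on both genotypes and add to the overlap. Whether they were matched is not given in the sources used here.

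Whether the genotypes responded differently was tested on the difference of their log2 ratios, in which a constant dye effect cancels. At 12 h 3 of 10 ubiquitin probes were higher in the resistant response past the threshold over all probes and 7 were not called. Adjusted over the list alone 7 of 10 passed. For one KIQDKEGI probe the log2 ratio was 1.61 ± 0.50 in resistant and 0.41 ± 0.10 in susceptible lines, a difference of 1.21 (SE 0.28, adjusted p = 0.0221). The MQIFVKTLTGK probe that passed differed by 1.14 (SE 0.32, adjusted p = 0.0437), and its near-copy, shifted by a base, was not called. The other called KIQDKEGI probe, with a difference of 0.91, shares its sequence with a probe that was not called. The P450 probe with PFGSGRRVCPG stood at 0.78 ± 0.23 in resistant and -1.02 ± 0.44 in susceptible lines, a difference of 1.80 (SE 0.43, adjusted p = 0.025). With slide as a block the P450 probe differed by 1.48 (adjusted p = 0.351) and the KIQDKEGI probe by 1.13 (adjusted p = 0.264), and none of the ubiquitin probes passed. Without line 46 or 51 the P450 and KIQDKEGI calls were also lost. None of the WRKY, NBS, EF-hand, kinase or light-harvesting probes differed between genotypes at 12 h past the threshold, and the medians of the WRKY and NBS differences were 0.60 and 0.35. The class test called ubiquitin higher in the resistant response (camera, adjusted p = 0.00195; adjusted p = 0.898 with an estimated correlation; adjusted p = 0.00151 with slide as a block, where the difference rests on a single susceptible array).

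Of all probes 1358 were higher and 1161 lower in the resistant than in the susceptible response at 12 h. Among these 2519 probes 937 were called against non-inoculated leaves in resistant lines alone, 881 in susceptible lines alone, and 289 in both with opposite sign. By the naming rule the probes with the largest differences were Gmax_090518_3232 (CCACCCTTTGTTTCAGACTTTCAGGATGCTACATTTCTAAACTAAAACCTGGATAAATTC) and CUST_22895_PI399485623 (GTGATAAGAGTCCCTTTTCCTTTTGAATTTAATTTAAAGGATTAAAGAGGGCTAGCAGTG). Gmax_090518_3232 stood at 2.37 ± 0.83 in resistant and -1.86 ± 0.52 in susceptible lines (difference 4.22, SE 0.69, adjusted p = 0.0038). CUST_22895_PI399485623 stood at 2.58 ± 1 and -1.30 ± 0.76 (difference 3.88, adjusted p = 0.00583). In the opposite direction CUST_1457_PI399485623 (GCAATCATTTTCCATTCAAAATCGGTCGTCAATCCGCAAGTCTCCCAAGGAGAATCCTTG) stood at -2.20 ± 0.67 and 2.72 ± 1.07 (difference -4.92, adjusted p = 0.00207). CUST_6011_PI399485623 (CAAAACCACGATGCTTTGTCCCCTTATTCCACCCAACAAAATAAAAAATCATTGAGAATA) stood at -1.75 ± 0.57 and 3.05 ± 1.73 (difference -4.80, adjusted p = 0.00835). With slide as a block CUST_1457_PI399485623 passed, while Gmax_090518_3232 (4.54, adjusted p = 0.0903), CUST_22895_PI399485623 (3.09, adjusted p = 0.177) and CUST_6011_PI399485623 (-3.92, adjusted p = 0.256) did not. Of all probes 161 passed with this block, 34.2% of them higher in the resistant response, and on the 1 slide that held both genotypes at 12 h, with a single susceptible array, 230 passed. Median centring turned the share of probes higher in the resistant response from 53.9% to 44.9%. From the 12 h arrays alone 973 passed, array weights gave 8128, and without line 46, 50, 51 or 52 the count was 539, 1589, 1223 and 580.

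**Figure D3:**
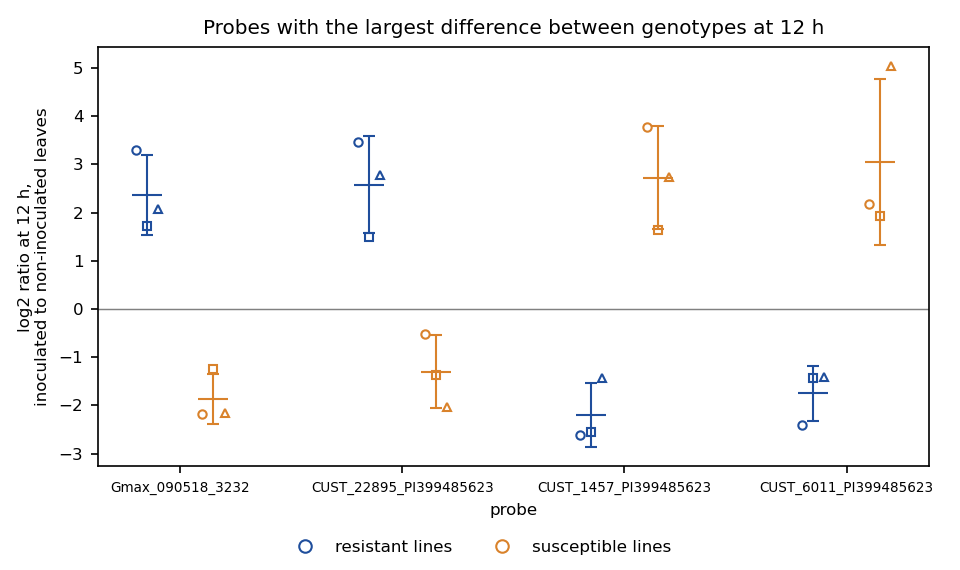
Log2 ratios at 12 h (vertical axis) of the 4 named probes (horizontal axis), with an open symbol per array and line, resistant lines in blue and susceptible lines in orange, and bars for the mean ± SD of 3 arrays. In each probe the arrays of one genotype lie above 0 and those of the other below 0.

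At 3 h no probe differed between the resistant and susceptible responses (limma, 0 of 39597; 1889 at an unadjusted p under 0.05), and the smallest adjusted p was 0.223. The ubiquitin median difference was 0.13 and that of the light-harvesting probes 0.12. Between 1 and 4 probes passed under single alternatives, with 1 for median centring, 2 for array weights, 1 for slide as a block and 4 within the slide that held both genotypes. With slide as a block the class test also called ubiquitin higher (median 0.43, adjusted p = 0.0242) and histones lower (median -0.76, adjusted p = 0.00923) in the resistant response at 3 h, where the fit without it gave adjusted p = 0.425 and 0.0827. With an estimated correlation that fit gave adjusted p = 0.965 and 0.898, and the blocked difference rests on a single resistant array.

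At 3 days 11 probes differed, 7 higher and 4 lower in the resistant response. None of the motif probes did, with median differences of -0.10 for ubiquitin, 0.58 for EF-hand and -0.75 for light-harvesting probes. The count was 2 with line as a random block, 50 with slide as a block and 60 within the 1 slide that held both genotypes, with a single susceptible array. Of these 6% and 8.3% were higher in the resistant response, against 63.6% of the 11. With slide as a block the EF-hand class was called higher in the resistant response (median 1.02, adjusted p = 0.00196; adjusted p = 0.12 without the block and 0.96 with an estimated correlation), a difference that rests on the single susceptible array of that slide. The count was 0 with only the groups compared, 1 without background subtraction, and 2 with processed signals, deposited values or median centring. Array weights gave 225 probes. Without line 46 or 52 the count rose to 171 and 31, and without line 49, 50 or 51 it was 1, 0 and 2.

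The course of each response was tested on differences between times within a genotype. From 3 h to 12 h the clock motif probe rose by 5.75 (SE 0.48) in resistant and 5.20 (SE 0.48) in susceptible lines, and the ratios of 3 of 4 light-harvesting probes rose in both, by 3.55 to 4.34 and 3.77 to 4.79. Not all of this lay in the Cy5 channel. Over the 6 lines the Cy5 level of these probes rose by 2.79, 1.89 and 1.33 while the Cy3 level changed by -1.77, -2.46 and -2.33, and the reason for the lower Cy3 signal was not settled. The HRDLKPDNLL kinase probe fell by 1.25 and 1.18 on the log2 scale, and these calls were lost without line 46 and without any susceptible line. Of the ubiquitin probes 2 of 10 rose in resistant lines (median 0.52), neither of them with median centring, and 0 of 10 in susceptible lines (median -0.20). From 3 h to 3 days the ratio of the WRKYGKK probe rose by 1.67 (SE 0.39) and 1.90 (SE 0.39). The ratios of both NGRLAMFS probes rose in both genotypes, but none of these calls held with slide as a block. No slide held 3 h and 3 day arrays of the same genotype. That fit thus compared the times through arrays of the other genotype, and the lost calls speak neither for nor against slide. Over the 6 lines the Cy5 level of the NGRLAMFS probes rose by 1.7 and 0.76 while their Cy3 level changed by -1.96 and -2.45. The ubiquitin class was shifted upward from 3 h to 3 days in resistant (camera, adjusted p = 0.00809) and susceptible lines (adjusted p = 7.46e-06), and so was the NBS class (adjusted p = 0.0164 and 0.0278), of which 1 and 0 probes passed singly. Of the 10 ubiquitin probes 0 and 3 passed singly. With an estimated correlation the ubiquitin values were adjusted p = 0.898 and 0.866, and the NBS values adjusted p = 0.898 in both. With line as a block the NBS shift in susceptible lines had adjusted p = 0.0551.

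In resistant lines 4216 probes rose and 2693 fell from 3 h to 12 h, and 1426 rose and 1233 fell from 3 h to 3 days. In susceptible lines the numbers were 2161 and 1033, and 647 and 528. Median centring changed the share of rises from 61% to 50.2% and from 53.6% to 67.5% in resistant lines, and from 67.7% to 39.2% and from 55.1% to 43.1% in susceptible lines. In susceptible lines from 3 h to 12 h the share was 57.5% with the scanner's processed signals and 55.9% with the deposited value table. With line as a block the totals of 2659, 3194 and 1175 became 6238 for resistant lines at 3 days, 5299 for susceptible lines at 12 h and 3430 for susceptible lines at 3 days. With slide as a block the 3 day totals were 230 and 1, and within the compared arrays alone 178 and 280. Array weights gave 10746 for resistant lines at 12 h, and 6763 and 4617 for susceptible lines at 12 h and 3 days. Leaving out a line changed the resistant totals from 6909 to 3823 and 3584 at 12 h (without 46 and 47) and from 2659 to 1692, 472 and 269 at 3 days (without 46, 47 and 49). The susceptible totals went from 3194 to 1098, 2056 and 1342 at 12 h and from 1175 to 329, 135 and 374 at 3 days (without 50, 51 and 52). All 12 h arrays lay on slides without 3 h or 3 day arrays, so slide could not be fitted as a fixed block there. No slide held 3 h and 3 day arrays of the same genotype either. The 3 day totals with slide as a block therefore rest on single arrays of the other genotype. These were susceptible line 50 on slide 5 for resistant lines and resistant line 49 on slide 2 for susceptible lines. Both channels share a slide, and the 309 probes that changed in Cy3 from 3 h to 12 h were 0.039 of the 7890 in Cy5. This argues against a slide or scan effect common to both channels, which would in any case largely cancel in the ratios. An effect of slide or scan on Cy5 alone would leave Cy3 unchanged and stays open. From 3 h to 3 days 4576 probes changed in Cy3 and 8333 in Cy5, so this argument does not reach the 3 day comparisons.

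Constitutive differences were tested on the Cy3 level of non-inoculated leaves, averaged over the 3 arrays of each line. No motif probe passed, and the median differences between resistant and susceptible lines were -0.26 for ubiquitin, -0.01 for WRKY, -0.17 for NBS and 0.34 for light-harvesting probes. In all 77 probes were higher and 79 lower in resistant lines. The largest differences by the naming rule were 3.55 (SE 0.25, adjusted p = 0.00273), from means of 13.1 ± 0.31 and 9.55 ± 0.28, and -4.56 (SE 0.49, adjusted p = 0.015), from 9.78 ± 0.35 and 14.35 ± 1.01. With all 9 and 9 arrays and line as a random block 1126 probes passed, and 655 with slide added. A separate fit of only the probes well above background on all arrays called 45, array weights gave 252, and without line 46, 49, 50 or 52 the count was 41, 51, 72 and 52.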

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

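Each result here was flagged because the responses of resistant and susceptible lines differed by a test of the difference itself. The tests within single slides and without the dim array, and in the part on other observations the tests of the clock probe alone and of competition for spots, were chosen after the values had been seen. At 12 h 2519 probes differed and at 3 days 11. Among motif probes at 12 h, a homeodomain probe (WFQNRRAR) was higher in the resistant response by 0.92 on the log2 scale (adjusted p = 0.0476), although it was not well above background on all arrays. The cytochrome P450 probe was higher by 1.8, and 3 ubiquitin probes by 1.21, 1.14 and 0.91. The ubiquitin probes at 1.14 and 0.91 each have a copy or near-copy that was not called. By the naming rule Gmax_090518_3232 differed by 4.22, CUST_22895_PI399485623 by 3.88, CUST_1457_PI399485623 by -4.92 and CUST_6011_PI399485623 by -4.8. Only CUST_1457_PI399485623 still passed with slide as a block, at -5.98 (adjusted p = 0.0183). The motif probes kept their sign at 1.12, 1.48, 1.13, 1.15 and 1.06 in the order given, with adjusted p from 0.23 to 0.352.

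More probes differed between the responses at 12 h than at 3 h or 3 days, and slide, a dim array and control leaves were weighed as technical causes. With slide as a block the median difference of the called probes went from 1.53 to 1.44, a ratio of 0.94, but this difference rests on a single susceptible array, that of line 50, and on probes selected with it. The number past the threshold fell to 161, a loss that goes with the single array left and speaks neither for nor against slide. Slide 4 holds the other susceptible 12 h arrays and no resistant one, so slide and a difference between the genotypes cannot be told apart there and both stay open. Without the dim array of line 51 the count was 1533, and the Cy3 level of control leaves carried a share of 0.16 of the difference (0.24 in Cy3, 1.29 in Cy5), which argues against the dim array or control leaves as the whole cause.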

How the results depend on the processing

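Of 240 alternative counts 155 were within 1.5 times the main one. Of 2753 alternative values of called motif and named probes 2255 kept their call, 498 lost it and 0 changed sign. Signal over background and 3 lines per group limit every count, and dropping dim probes moved 2 of the 14 counts by over 1.5 times. The cause of the changes below was not tested, except where fewer samples or a stricter limit make them.

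Without background subtraction susceptible 3 h counted 7949, the 3 day difference of responses 1 and susceptible 3 days against 3 h 1783. Scanner-processed signals gave 7070 for susceptible 3 h and 2 for the 3 day difference. The values deposited by the authors gave 7168 for susceptible 3 h and 2 for the 3 day difference. Median centring gave 1 for the 3 h and 2 for the 3 day difference, and offset 16 gave 3 for the latter. Median centring also turned the side with more probes. The share of rises went from 58.1% to 48.4% in resistant leaves at 3 h, from 55.1% to 46.6% in resistant and from 55% to 44.1% in susceptible leaves at 12 h, from 53.9% to 44.9% for the 12 h difference of responses, and from 67.7% to 39.2% and from 55.1% to 43.1% in the susceptible comparisons of 12 h and 3 days with 3 h, so that the balance of rises and falls there rests on the normalization. In susceptible leaves at 3 h it went from 64.2% to 80.1%, for resistant 12 h against 3 h from 61% to 50.2% and for resistant 3 days against 3 h from 53.6% to 67.5%. The scanner-processed signals and the deposited values also turned the side at 12 h, to 49.3% and 47.7% rises in resistant and 47.3% and 46.5% in susceptible leaves, and both gave 48% in susceptible leaves at 3 days. For the 12 h difference of responses the share was 42.7% with only the groups compared, 44.4% without line 51 and 34.2% with slide as a block. No statement on more rises than falls at 12 h is therefore secure. Only probes well above background everywhere left 6 for the 3 day difference and 45 for non-inoculated leaves. A limit of 2-fold left 1881, 9665 and 4129 in resistant and 1719, 9614 and 3514 in susceptible leaves at 3 h, 12 h and 3 days. Array weights gave 7673 for susceptible 3 h, 11612 for susceptible 3 days, 2, 8128 and 225 for the differences of responses, 10746 for resistant 12 h against 3 h, 6763 and 4617 for the susceptible time comparisons and 252 for non-inoculated leaves. With only the groups compared the counts were 0 and 234 for resistant 3 h and 3 days, 0 and 74 for susceptible, 973 and 0 for the 12 h and 3 day differences, and 178 and 280 for 3 days against 3 h.

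The lines pair the arrays of different times by label. With the replicate block as a random effect (correlation 0.28) the 3 day difference counted 2, and no other count of this fit moved by over 1.5 times. As a fixed effect it gave 6238 for resistant 3 days against 3 h, and 5299 and 3430 for susceptible 12 h and 3 days against 3 h. For non-inoculated leaves 9 and 9 arrays with line as a block gave 1126, and 655 with slide added. Both counts rest on repeat arrays of 3 lines per genotype and can be too high. Slide as a random block (correlation -0.09) gave 4777 for susceptible 3 h. Slide as a fixed block gave 1, 161 and 50 for the differences of responses at 3 h, 12 h and 3 days, and 230 and 1 for 3 days against 3 h in resistant and susceptible lines. Within single slides the differences counted 4, 230 and 60, and the dimmest array left out gave 1533 at 12 h. Of the class tests 10 passed, 0 with an estimated correlation and 18 with motifs of both strands.

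Leaving out one line at a time gave 395 to 1890 for resistant 3 h, 11595 to 13996 for resistant 12 h, 3472 to 6632 for resistant 3 days, 50 to 2555 for susceptible 3 h, 11008 to 12556 for susceptible 12 h and 3013 to 3783 for susceptible 3 days. The differences of responses ranged from 0 to 0, 539 to 2437 and 0 to 171, resistant 12 h and 3 days against 3 h from 3584 to 5101 and 269 to 1692, the susceptible ones from 1098 to 2056 and 135 to 374, and non-inoculated leaves from 41 to 188.

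Not run were the fixed gene lists, the test of neighbouring genes, and slide as a fixed block for 12 h against 3 h, where no slide holds both times. For 3 days against 3 h no slide holds both times of a genotype, so that block compares them through arrays of the other genotype.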

Other observations

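The probes of this and the next paragraph and the tests of the clock probe alone and of competition for a spot were chosen after their values were seen. Ratios at 12 h in resistant lines were ranked among probes well above background on all arrays and of the same sign on all 3 arrays. The largest measured ones, given below, were in stretches known from a single photosynthesis protein. Saturation can hide larger ones, and the saturated MYB probe of the next paragraph stood at 6.74 or more. A probe with the sequence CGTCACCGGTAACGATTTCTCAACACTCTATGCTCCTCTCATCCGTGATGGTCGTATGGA, which encodes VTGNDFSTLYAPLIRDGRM, rose by 6.97 ± 0.23 in resistant and at least 6.75 ± 0.47 in susceptible lines, where Cy5 was saturated on 1 of 3 arrays. Another, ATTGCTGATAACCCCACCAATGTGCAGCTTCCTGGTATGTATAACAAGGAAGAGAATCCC, encodes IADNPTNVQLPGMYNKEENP and rose by 6.94 ± 0.40 and 7.00 ± 0.33. Both stretches are known from Rubisco activase, though the files name no gene. These probes may thus measure the same transcript and are not separate evidence. The second had already risen at 3 h, by 1.24 ± 0.88 in resistant and 2.86 ± 0.60 in susceptible lines. In susceptible lines the largest measured ratio at 12 h by the same rule was that of a probe of unknown protein, at least 7.67 ± 1.08 with Cy5 saturated on 3 of 3 arrays. Its Cy5 was also saturated on 3 of 3 arrays at 3 h in both genotypes, with ratios of 1.52 ± 1.25 in resistant and 2.95 ± 2.94 in susceptible lines. The next measured ratio was that of a probe shifted by a base from the second one above (7.04 ± 0.26). Saturated probes given as at least a value could lie higher, so this order is not settled.

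A further probe, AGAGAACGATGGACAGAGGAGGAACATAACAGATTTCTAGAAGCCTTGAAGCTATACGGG, encodes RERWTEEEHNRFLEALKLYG, a stretch of MYB factors of the LHY and REVEILLE kind. At 12 h it rose at least 107-fold in resistant lines (6.74 ± 0.12, Cy5 saturated on 3 of 3 arrays) and by at least 6.06 ± 0.70 in susceptible lines (saturated on 1 of 3). At 3 h it stood at -0.31 ± 0.33 and -0.07 ± 0.29 and did not pass, and at 3 days it fell to -1.33 ± 0.38 and -1.11 ± 0.57.

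The clock and light-harvesting probes raised the question whether inoculated and control leaves at 12 h were sampled at different times of day. If one control extract per line had served all times, the Cy3 level should hardly move between arrays. The median ratio of Cy3 to Cy5 change over the 5 probes was -1.301, so that Cy3 moved by more than 0.5 of the Cy5 change, although in the other direction. From 3 h to 12 h the Cy3 level of 3 of the 4 light-harvesting probes changed by -1.77 ± 0.55, -2.46 ± 0.79 and -2.33 ± 0.75 (log2, SD, 6 lines) while the Cy5 level rose by 2.79 ± 0.80, 1.89 ± 0.81 and 1.33 ± 0.67. These falls exceed their spread and argue against a single unchanged control extract for both times at these 3 probes, as far as competition for the spot, left open below, did not lower Cy3. The fourth, NGRLAMLA, with Cy5 saturated on 4 of the 18 arrays, changed by -0.77 ± 0.81 and 0.14 ± 0.32. For the clock probe alone the ratio was 0.06 (Cy3 0.35 ± 0.31, Cy5 5.82 ± 0.45), which is consistent with a control not matched in time of day. Whether separate control extracts were matched in time of day stays open. From 3 h to 12 h 309 probes changed in Cy3 and 7890 in Cy5, a ratio of 0.039. This argues against a slide or scan effect common to both channels. One on Cy5 alone would leave Cy3 unchanged, so the ratio cannot decide on it. Between 3 h and 3 days the numbers were 4576, of which 677 changed at least 2-fold, and 8333, of which 4988 did. The Cy3 signal thus also shifted between these times, and slide and a change in the control leaves cannot be told apart there.

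Competition of both labelled RNAs for a spot could lower Cy3 where Cy5 rises. Among 953 probes whose Cy5 level rose by over 2 log2 units the median Cy3 change was -0.26 in brighter and -0.18 in dimmer ones, against -0.01 and -0.05 among 24889 probes that stayed. The resulting value of -0.12 lay between both predictions and leaves competition open.

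A constant dye effect could add to the calls at 3 h, since no dyes were swapped. Probes called in resistant leaves at 3 h had a median of 0.64 in susceptible leaves at 3 h and 0.47 at 3 days, a ratio of 0.73. A dye effect alone predicts 1, and a ratio under 0.5 had been set in advance as arguing against it. A response that lasts to 3 days would also give a high ratio, so the ratio cannot tell it from a dye effect. Of 268 probes called with the same sign in all 6 groups (209 up, 59 down), 29.9% were also called between times or genotypes, where such an effect cancels, and the share stays open between both predictions. Arrays of a line may share a control, which would also give calls common to all times, as would a lasting response.

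Groups were also rearranged, with too few splits for a share under 0.05 in any comparison. For inoculated against non-inoculated leaves the sign of single arrays was turned, and 1 of 4 patterns, the real one, called as many probes in each of the 6 comparisons. The highest other counts were 0, 11 and 0 in resistant lines at 3 h, 12 h and 3 days (real 3903, 16508 and 7839) and 0, 8 and 1 in susceptible lines (real 3001, 16219 and 6790). For the difference of responses at 3 h 10 of 10 splits called as many as the real one (0, highest other 0). At 12 h it was 1 of 10 (2519, highest other 0). At 3 days it was 2 of 10 (11, highest other 891), and the other split set resistant line 46 with susceptible lines 50 and 51 against the rest, so the samples hold structure beside genotype. Between times it was 1 of 10 each, with real counts of 6909, 2659, 3194 and 1175 and highest others of 0, 0, 1 and 0 for resistant 12 h, resistant 3 days, susceptible 12 h and susceptible 3 days against 3 h. For non-inoculated leaves it was 1 of 10 (156, highest other 52, for lines 46, 49 and 50 against the rest).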
